A study of Homo sapiens with 6 samples.

How the data were processed

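RNA sequencing of total RNA was analysed in 6 libraries of human macrophages derived from peripheral blood mononuclear cells: 3 untreated and 3 treated with Phago-Act. Per the labels' protocols, cells were grown with M-CSF for 5 days and then treated for 2 days, RNA was extracted with Trizol, and libraries followed a standard protocol of the sequencing provider BGI. Groups and donor numbers were taken from the sample titles. In 1 of the 3 pairs the sample numbers inside the files run in the other order than in the remaining pairs; the labels were followed. Replicates are separate donors.

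The authors deposited 1 table per library with FPKM values to 2 decimals for 16404 genes, per the file headers, each with a gene number, a symbol and a gene type (16260 of them mRNA). Of the gene numbers, 16185 matched a human gene in the NCBI RefSeq gene table. Per the submitters' processing notes, R 3.3.3 and DESeq2 were used and the build was mm9, which is a mouse build, while the gene numbers and symbols are human. For that reason no genome coordinates are given. The aligner, the counting tool and the annotation are not given in the sources used here, and neither is whether strand was used, so values of paralogs, overlapping genes and antisense genes can share reads. FPKM are scaled to each library's total, so a large rise of a few genes lowers all others; the 10 genes with the highest values took 18.2% to 21.6% of the summed FPKM.

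The design foresaw a count model for counts and, for normalised values, limma on a log scale. As the files hold FPKM, limma was used. Genes on the Y chromosome, XIST and TSIX were removed before any step, which left 16393 genes. Genes with at least 1 FPKM in at least 3 libraries were tested (10697). The test was limma-trend (limma 3.58.1, R 4.3.3; empirical Bayes with a mean-variance trend, 2-sided) on log2(FPKM + 1), with the donor number as a block, because the study's design text states that treated and untreated cells were donor-matched. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates changes of weakly expressed genes. With the block the fit had 2 residual degrees of freedom and 2.33 prior ones, without it 4 and 2.54. The pairing was also checked in the data: the deviations of the libraries of a donor from their group means had correlations across genes of 0.213, 0.252 and -0.0903 in replicates 1, 2 and 3. Donor accounted for 28.8% of the total sum of squares, treatment for 45.8% and the remainder for 25.4%. With the remainder that close to the donor share, these values do not establish the pairing, and the block rests on the design text. The Phago-Act library of replicate 2 correlated most with its own untreated library (0.916, against 0.889 and 0.911). Those of replicates 1 and 3 did not.

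A set of 36 gene lists was fixed before the data were examined, covering interferon responses, antigen presentation, cytokines, macrophage states, phagocytosis, metabolism, general cell functions and markers of other cell types. The 32 lists with at least 5 measured genes were tested with camera (preset inter-gene correlation 0.01), adjusted over the lists, and again with an estimated correlation and with fry. Counts "adjusted over the list alone" apply Benjamini-Hochberg within a list. The genes named were also fixed by a rule before the data were examined. From genes past the threshold with a mean of at least 5 FPKM in the higher group and the same sign in all 3 donors, the 12 highest and 12 lowest fold changes were taken. In each list up to 4 called members with the largest changes and up to 2 that moved the other way were added, as well as members needed to describe a list with few calls. SIRPA, SIRPB1, SIRPG, CD47, PTPN6 and PTPN11 were named in any case. Genes whose level is often set by an inherited deletion, haplotype or copy number were counted but not named. IDO1, MX1, CIITA, IL1B and CD40 were chosen as list members after their values were seen.

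The test was checked on simulated data with 200 changed genes among 10697, in 20 simulations. With the donor block, 33.5% of genes with a log2 fold change of 1 were recovered, 94% of those at 2 and 99.2% of those at 4, and 7.3% of calls were false. Without the block these were 13.7%, 82.2%, 97.3% and 1.3%. The simulated noise was independent between genes and libraries, and no simulated library was set apart as the Phago-Act library of replicate 3 was. These shares therefore need not hold for the real libraries.

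The absolute depth of the libraries is not given in the sources used here. Low FPKM values of short transcripts (under 1500 bases, under 3 FPKM in every library) were compared between libraries, since whole reads give whole multiples of a common step. Relative to the untreated library of replicate 1, the most frequent ratio gave a depth of 1.00 for both libraries of replicate 3. It gave 1.12 for the untreated library of replicate 2 (95% bootstrap interval 0.796 to 1.17), 1.19 for the Phago-Act library of replicate 1 (0.758 to 1.22) and 1.19 for that of replicate 2 (1.09 to 1.39), so the first of these intervals and the second include lower as well as higher depths than the reference. These estimates rest on 136 to 154 genes, of which 8.8% to 18% lay within 0.05 log2 units of the most frequent ratio, and rounding to 2 decimals favours a ratio of 1. No 2 libraries were near copies: their correlations on the log2 scale were between 0.889 and 0.979, and at most 7.8% of values were identical. None of the ribosomal protein or reference genes examined was listed at 0.

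Alternatives planned before the data were examined were the fit without the donor block, a pseudocount of 0.1, no filter on low values, each donor left out in turn, and a threshold of 0.01. Alternatives that need counts were not run. Added after seeing the data were upper-quartile, median-of-ratios and TPM scaling of the FPKM, a filter of 5 FPKM, limma without the trend, and fits without the block that left out the Phago-Act library or both libraries of replicate 3. Transcript length and GC content were those of the longest GENCODE v29 transcript of each gene. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.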

Results

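The series measured gene expression by RNA sequencing in human macrophages cultured from peripheral blood mononuclear cells. Cells of 3 donors were differentiated for 5 days with macrophage colony-stimulating factor (M-CSF), the growth factor that drives monocytes to become macrophages. For each donor, 1 library came from untreated cells, which the labels name SIRPα normal, and 1 from cells treated for 2 days with Phago-Act, which the labels name SIRPα low. For the untreated cells no culture time beyond the 5 days is recorded. If they were not kept for the same 2 further days, treatment and culture time cannot be told apart. The composition of Phago-Act is not given in the sources used here. The 6 libraries therefore form 3 donor-matched pairs, called replicates 1 to 3 after the donor number. Values were FPKM (fragments scaled to transcript length and to the mapped fragments of the library) and summed to between 475062 and 495095 per library. Between 10311 and 10709 genes per library reached 1 FPKM. The number of reads behind each library is not given in the sources used here, so no counting interval is attached to any value.

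SIRPA (gene ID 140885) encodes SIRPα, the inhibitory macrophage receptor for the surface protein CD47, and is the gene the group labels refer to. Its mRNA was 151 ± 7.44 FPKM in untreated libraries and 225 ± 48.9 FPKM in the libraries labelled SIRPα low (SD, n = 3 each). The log2 fold change was 0.55 (SE 0.18, limma adjusted p = 0.204), so the gene did not pass the test, and the value was higher in the Phago-Act library in 3 of 3 replicates. The mRNA therefore did not separate the groups in the direction of their label. Directions below are given for the libraries labelled Phago-Act against those labelled untreated. CD47 itself stood at 24.3 ± 6.11 and 25.5 ± 4.89 FPKM (log2 fold change 0.08, SE 0.22). PTPN6 and PTPN11, the genes of the phosphatases SHP-1 and SHP-2 that SIRPα recruits, had log2 fold changes of 0.35 (SE 0.16) and -0.19 (SE 0.17). SIRPB1, a paralog that shares sequence with SIRPA and whose reads may not be separable from it, had a log2 fold change of 0.26 (SE 0.19, adjusted p = 0.506, and 0.0464 without replicate 3). SIRPG was at 0.473 ± 0.294 and 0.673 ± 1.17 FPKM and below the filter on low values. In the list of the SIRP family, CD47, the SHP phosphatases and other inhibitory receptors, 1 of 12 measured genes passed, and 3 did when adjusted over the list alone. Without replicate 3, 3 were called higher and 3 lower. The gene that passed in the main fit was LILRB2, an inhibitory leukocyte receptor for MHC class I, which fell from 473 ± 167 to 77.4 ± 17.2 FPKM (log2 fold change -2.56, SE 0.17, adjusted p = 0.026).

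The question of the comparison was which transcripts differ between macrophages with and without Phago-Act. The 12 called genes with the highest fold changes included the chemokines CXCL9, CXCL10, CXCL11 and CCL19 and the guanylate-binding proteins GBP5, GBP4 and GBP1, and those with the lowest included F13A1, ENPP2, MARCO and HS3ST1. CXCL9 (gene ID 4283), a chemokine that attracts activated T cells, rose from 41.5 ± 31.0 to 2161 ± 1141 FPKM (log2 fold change 5.99, SE 0.42). F13A1 (gene ID 2162), the A chain of coagulation factor XIII and a marker of alternatively activated macrophages, fell from 230 ± 188 FPKM and was listed at 0, 0 and 0.11 FPKM in the Phago-Act libraries (log2 fold change -7.49, SE 0.44). Among 10697 genes tested, 65 were higher and 48 lower at an adjusted p under 0.05 in limma with the donor as a term. All 113 of these changed at least 2-fold and had the same sign in all 3 replicates. The same sign in all replicates held for 45.1% of the genes tested, against 25% expected by chance. Without the donor term 180 genes were higher and 176 lower, of which 56 and 44 were among those called with it. The counts also depended on which replicate was left out: without replicate 1 or without replicate 2 limma called 0 genes (1076 and 892 at an unadjusted p under 0.05), and without replicate 3 it called 1367 higher and 1459 lower. Each of these fits has 1 residual degree of freedom, and all 113 genes were still called without replicate 3. The fit without replicate 3 called 2826 of 10697 genes, or 1249 without the donor term. Counts of list members called without replicate 3, above and below, are to be read against these totals. With no filter on low values limma also called 0 of 16374 genes (2713 at an unadjusted p under 0.05), and 0 genes passed an adjusted p under 0.01 in the filtered set.

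**Figure D1:**
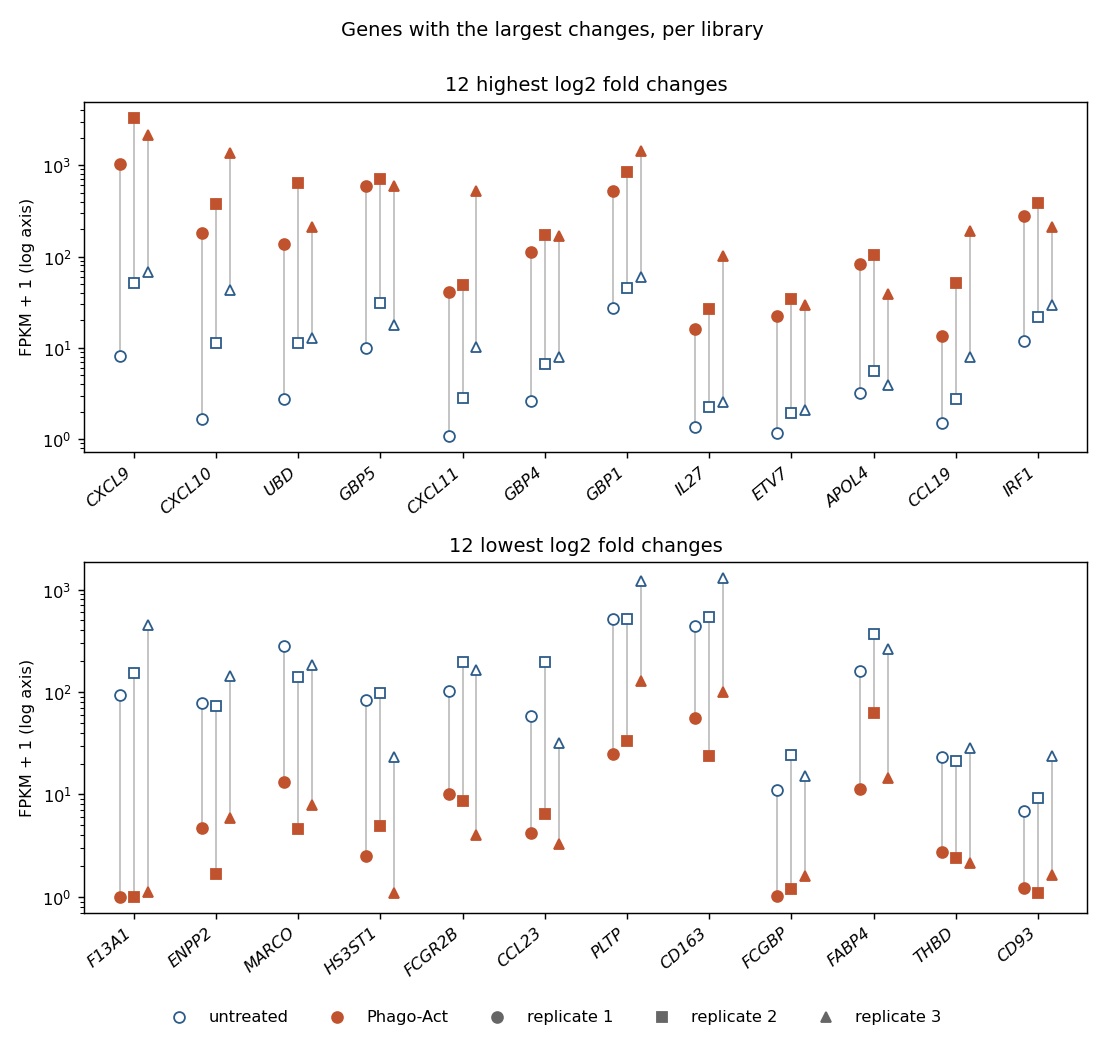
FPKM + 1 on a log axis for the 12 genes with the highest (upper panel) and the 12 with the lowest (lower panel) log2 fold changes, 1 point per library (n = 3 per group); open blue symbols are untreated libraries, filled orange symbols Phago-Act libraries, the symbol shape gives the replicate, and a grey line joins the libraries of 1 donor. Each gene moved the same way in all 3 replicates; CXCL9 went from 7.24, 49.8 and 67.5 FPKM to 1026, 3309 and 2147 FPKM.

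Genes induced mainly by interferon gamma formed the group with the most calls. Of 41 measured, 21 rose and 0 fell, 36 rose when adjusted over the list alone, and 37 had a positive change in all 3 replicates. Without replicate 3, 41 were called higher. CXCL10, like CXCL9 a ligand of CXCR3, a chemokine receptor on T cells, rose from 17.7 ± 21.5 to 645 ± 640 FPKM (log2 fold change 5.61, SE 0.41). UBD, a ubiquitin-like modifier, rose by a log2 fold change of 5.17 (SE 0.41), and the guanylate-binding proteins GBP5, GBP4 and GBP1, interferon-induced GTPases of cell-autonomous defence, rose by 5.15 (SE 0.30), 4.85 (SE 0.25) and 4.35 (SE 0.16). GBP genes are close paralogs, and reads may be shared among them. The transcription factors ETV7 and IRF1 rose by 4.07 (SE 0.16) and 3.84 (SE 0.38), IRF1 from 20.2 ± 8.82 to 293 ± 90.7 FPKM. APOL4, an apolipoprotein L gene outside the list, rose by 4.07 (SE 0.31). IDO1, the tryptophan-degrading enzyme, stood at 3.23, 64.5 and 35.8 FPKM untreated and 1264, 2171 and 812 FPKM with Phago-Act (log2 fold change 5.91, SE 0.81, adjusted p = 0.069, and 0.036 without the donor term). The median log2 fold change of the list was 2.44, and 3.22, 3.00 and 2.03 in replicates 1, 2 and 3. In camera the list was higher than other genes (adjusted p = 3.25e-35), a call lost with an estimated correlation (adjusted p = 0.450). None of the 15 list calls that camera made with its preset correlation was kept with an estimated correlation. In that form camera tests on the 2 residual degrees of freedom of the fit, which leaves little power for any list. NADPH oxidase genes and fibroblast, endothelial and epithelial markers had estimated correlations of -0.0487 and -0.0823, below the preset, and also lost their calls. A call lost there therefore does not show that a list was unchanged. The other called lists had estimated correlations above the preset of 0.01. These ran from 0.0485 for inflammatory chemokines through 0.168 for interferon gamma genes to 0.796 for ribosomal protein genes and 0.964 for type I interferon genes. For such lists the adjusted p with the preset correlation can be too small, because it assumes a weaker correlation.

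Of 49 measured genes induced by type I interferon, 1 rose at adjusted p under 0.05, 5 did when adjusted over the list alone, 27 had a positive change in all 3 replicates, and 0 fell. The gene that passed was ISG20, an interferon-induced exonuclease (2.82 ± 2.81 to 43.1 ± 11.9 FPKM, log2 fold change 3.80, SE 0.37). The median log2 fold change was 2.58 and 1.98 in replicates 1 and 2 and 0.04 in replicate 3. MX1, an antiviral GTPase, went from 7.62 to 238 FPKM in replicate 1, from 20.1 to 162 FPKM in replicate 2 and from 154 to 219 FPKM in replicate 3 (adjusted p = 0.194). In camera the list was higher (adjusted p = 7.09e-16), with an adjusted p of 0.586 with an estimated correlation. Without replicate 3, 49 of the 49 genes were called higher, and 44 were without the donor term as well. With only the Phago-Act library of replicate 3 left out and no donor term, 4 were called higher.

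Of 21 measured genes of MHC class I presentation, 2 rose, 16 did when adjusted over the list alone, and 0 fell. TAP1, a subunit of the peptide transporter that loads class I molecules, rose from 65.2 ± 8.27 to 498 ± 54.6 FPKM (log2 fold change 2.92, SE 0.16). NLRC5, the class I transactivator, rose from 8.74 ± 0.251 to 31.6 ± 4.28 FPKM (log2 fold change 1.73, SE 0.15). Without the donor term 9 genes were called higher, and without replicate 3 the count was 18. The list was higher in camera (adjusted p = 2.28e-12, and adjusted p = 0.450 with an estimated correlation). Of 19 measured genes of MHC class II presentation, 0 passed, 0 did when adjusted over the list alone, and 3 had an unadjusted p under 0.05. Without replicate 3, 11 were called higher and 1 lower. The median of the class II list was 0.61, 0.55 and -0.62 in replicates 1, 2 and 3. Its adjusted p in camera was 0.285 (0.958 with an estimated correlation), and 0.000126 in the higher direction without replicate 3 with the preset correlation. CIITA, the class II transactivator, stood at 8.36, 11.7 and 25.4 FPKM untreated and 54.2, 78.2 and 32.3 FPKM with Phago-Act (adjusted p = 0.175).

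Of 24 measured inflammatory chemokines, 5 rose and 1 fell, and 9 rose and 1 fell when adjusted over the list alone. Besides CXCL9 and CXCL10, CXCL11, the third CXCR3 ligand, rose by a log2 fold change of 5.01 (SE 0.34) and CCL19, a ligand of the homing receptor CCR7, by 4.01 (SE 0.31). CCL23, a monocyte-attracting chemokine, fell from 93.5 ± 87.4 to 3.62 ± 1.59 FPKM (log2 fold change -3.99, SE 0.36). CXCL10, CXCL11 and CCL19 did not pass without the donor term (adjusted p = 0.068, 0.077 and 0.093), and 3 chemokines were higher there. Of 12 measured proinflammatory cytokines, 3 rose, 6 did when adjusted over the list alone, and 0 fell. TNF rose from 29.04 ± 21.0 to 297 ± 52.6 FPKM (log2 fold change 3.51, SE 0.31), IL27 from 1.06 ± 0.630 to 47.1 ± 46.4 FPKM, and IL15, a survival factor of NK and memory T cells, from 0.80 ± 0.40 to 6.25 ± 1.31 FPKM. IL1B went from 244 to 12.6 FPKM and from 351 to 5.65 FPKM in replicates 1 and 2, and from 89.7 to 329 FPKM in replicate 3 (adjusted p = 0.418). Both lists were higher in camera (adjusted p = 0.000713 and 0.000259), and both had an adjusted p of 0.450 with an estimated correlation. Their medians in replicates 1, 2 and 3 were 1.02, 0.02 and 1.57 for chemokines and 2.18, 1.04 and 2.70 for cytokines. Without replicate 3, 11 chemokines were called higher and 3 lower, and 6 cytokines higher and 2 lower. Without both replicate 3 libraries and the donor term, the chemokine list was not called, although 10 of its genes were higher.

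Of 26 measured NF-κB targets and feedback regulators, 2 rose, 8 rose and 1 fell when adjusted over the list alone, and 1 was higher without the donor term. Without replicate 3, 10 were called higher and 4 lower. TNFAIP2 rose from 65.5 ± 19.7 to 584 ± 225 FPKM (log2 fold change 3.09, SE 0.17), and PTGS2, the gene of cyclooxygenase-2, rose by 2.58 (SE 0.21, adjusted p = 0.032, and 0.080 without the donor term). The median of this list was 0.17, 0.41 and 1.73 in replicates 1, 2 and 3, and its call in camera (adjusted p = 2.96e-06, and 0.481 with an estimated correlation) was lost when replicate 3 was left out of the fit without the donor term. Of 31 measured genes of inflammasomes and programmed cell death, 2 rose, 8 rose and 1 fell when adjusted over the list alone, and 6 were higher without the donor term. Without replicate 3, 19 were called higher and 1 lower. The 2 in the main fit were the death receptor gene FAS, from 3.05 ± 0.716 to 10.6 ± 0.98 FPKM (log2 fold change 1.54, SE 0.14), and PMAIP1, a p53-inducible activator of apoptosis, from between 1.19 and 1.31 FPKM in the untreated libraries to 8.48 ± 2.23 FPKM (log2 fold change 2.05, SE 0.18). That list was higher in camera (adjusted p = 9.32e-09, and adjusted p = 0.450 with an estimated correlation). Of 15 measured costimulatory and maturation genes, 0 passed in limma over all genes and 7 rose when adjusted over the list alone, as many as had an unadjusted p under 0.05. Without replicate 3, 9 were called higher and 1 lower. CD40 stood at 82.5, 125 and 58.3 FPKM untreated and 257, 361 and 603 FPKM with Phago-Act (log2 fold change 2.17, SE 0.43, adjusted p = 0.111, and 0.042 without the donor term). The costimulatory list and the 8 measured genes of the NADPH oxidase, of which 0 passed and 3 rose when adjusted over the list alone, were higher in camera (adjusted p = 7.2e-06 and 0.00408). For both, the adjusted p was 0.450 with an estimated correlation, and without replicate 3, 5 NADPH oxidase genes were called higher. CLEC4E, a receptor for mycobacterial glycolipids and the 1 call among 29 pattern recognition genes, rose from 1.82 ± 1.87 to 19.1 ± 5.97 FPKM (log2 fold change 3.01, SE 0.27). In that list 5 rose and 3 fell when adjusted over the list alone, 12 were called higher and 4 lower without replicate 3, and its adjusted p in camera was 0.0522, 0.0408 without the donor term and 0.902 with an estimated correlation.

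Of 41 measured markers of alternatively activated and tissue-resident macrophages, 4 fell, 23 did when adjusted over the list alone, and 0 rose. The other 37 did not pass over all genes. CD163, the haemoglobin scavenger receptor, fell from 753 ± 460 to 58.6 ± 37.9 FPKM (log2 fold change -3.73, SE 0.33). PLTP, a phospholipid transfer protein, fell from 749 ± 409 to 61.4 ± 57.9 FPKM (log2 fold change -3.86, SE 0.27), and MS4A4A, a tetraspan surface protein of macrophages, from 142 ± 35.6 to 39.9 ± 16.1 FPKM (log2 fold change -1.87, SE 0.20). MS4A4A did not pass without the donor term (adjusted p = 0.0501). The list was lower in camera (adjusted p = 1.6e-09, and 0.450 with an estimated correlation), and its median was -1.55, -2.16 and -2.19 in replicates 1, 2 and 3. Without replicate 3, 29 of its genes were called lower and 2 higher. Of 34 measured phagocytic receptors, 4 fell, 17 did when adjusted over the list alone, 9 did without the donor term, and 0 rose. Without replicate 3, 19 were called lower and 4 higher. MARCO, a scavenger receptor for bacteria and particles, fell from 200.1 ± 71.3 to 7.53 ± 4.38 FPKM (log2 fold change -4.63, SE 0.17). FCGR2B, the inhibitory Fcγ receptor, fell from 152 ± 47.5 to 6.60 ± 3.21 FPKM (log2 fold change -4.39, SE 0.42), with the reservation that its neighbours in the Fcγ receptor cluster are near-identical over long stretches. CD36, a scavenger receptor for oxidised lipids, fell from 393 ± 60.8 to 78.8 ± 13.2 FPKM (log2 fold change -2.30, SE 0.15), and GAS6, a bridging ligand for apoptotic cells, from 10.8 ± 3.77 to 2.14 ± 0.816 FPKM. The receptor list was lower in camera (adjusted p = 0.00016, and 0.450 with an estimated correlation).

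Other genes with low fold changes were ENPP2, the gene of autotaxin (97.4 ± 38.9 to 3.09 ± 2.19 FPKM, log2 fold change -4.71, SE 0.31), HS3ST1, a heparan sulfate sulfotransferase (log2 fold change -4.59, SE 0.20), FCGBP (-3.67, SE 0.26), and CD93, a C-type lectin-like receptor (-3.14, SE 0.30). Of 27 measured genes of lipid handling, 3 fell and 0 rose, and 4 fell and 2 rose when adjusted over the list alone. The 3 were PLTP, CD36 and FABP4, a fatty acid-binding protein (264 ± 104 to 28.3 ± 28.7 FPKM, log2 fold change -3.54, SE 0.36). Of 24 measured genes of matrix proteolysis and coagulation, 1 fell, 6 did when adjusted over the list alone and 5 did without the donor term. It was THBD, the gene of thrombomodulin (23.2 ± 3.69 to 1.42 ± 0.305 FPKM, log2 fold change -3.32, SE 0.19). Of 17 measured inhibitory ligands and immunoregulatory enzymes, 1 fell, and 4 rose and 4 fell when adjusted over the list alone. The gene that fell was ARG2, a mitochondrial arginase (9.20 ± 2.07 to 2.56 ± 0.541 FPKM, log2 fold change -1.51, SE 0.15). Without replicate 3, 10 lipid genes were called lower and 6 higher, 11 matrix genes lower and 3 higher, and 5 inhibitory genes lower and 5 higher. In camera, the lists of lipid handling, of matrix genes and of inhibitory ligands were not called (adjusted p = 0.932, 0.168 and 0.885).

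With all libraries and the donor term, gene groups of general cell function had no member past the test in limma over all genes. Without replicate 3 they had: 29 ribosomal protein genes were called lower, 18 proliferation genes lower, and 20 ER stress, heat shock and immediate early genes higher and 3 lower. Without the donor term as well, these counts were 7 lower, 0 lower, and 17 higher and 0 lower. Cytosolic ribosomal protein genes had a median log2 fold change of -0.39 (46 measured, 10 lower at an unadjusted p under 0.05, 0 when adjusted over the list alone), and proliferation genes one of -0.51 (40 measured, 13 lower at an unadjusted p under 0.05 and 7 when adjusted over the list alone). In replicates 1, 2 and 3 the medians were -0.52, -0.62 and -0.06 for ribosomal protein genes and -0.51, -0.85 and -0.22 for proliferation genes. Both lists were lower in camera (adjusted p = 1.5e-06 and 5.33e-06), with adjusted p of 0.790 and 0.481 with an estimated correlation. ER stress, heat shock and immediate early genes had a median of 0.58 (30 measured, 4 higher at an unadjusted p under 0.05, 2 when adjusted over the list alone), and of 1.38, 1.5 and -0.11 in replicates 1, 2 and 3. That list was higher in camera (adjusted p = 0.000845, and 0.481 with an estimated correlation). It pools unlike groups of genes, so its median does not show that ER stress genes as such rose. Camera called neither the 48 genes of oxidative phosphorylation, with a median of -0.04, nor those of glycolysis, the TCA cycle and NAD metabolism, lysosomes, cholesterol synthesis, metallothioneins and NRF2 targets, cytoskeletal engulfment or reference genes (adjusted p = 0.161 to 0.932). Adjusted over the list alone, 1 gene rose and 2 fell among metallothioneins and NRF2 targets, 1 rose in the TCA cycle and NAD list, and 0 passed in the others. Without replicate 3, 4 genes were called higher and 9 lower for glycolysis, 2 and 4 for the TCA cycle and NAD, 7 and 3 for lysosomes, 2 and 7 for cholesterol synthesis, 7 and 3 for metallothioneins and NRF2 targets, 0 and 6 for cytoskeletal engulfment, 2 and 6 for reference genes, and 0 and 1 for oxidative phosphorylation. Most of these calls were lost without the donor term as well. The counts were then, in the same order, 1 and 4, 1 and 2, 0 and 0, 0 and 4, 2 and 1, 0 and 2, 2 and 1, and 0 and 0. Among markers of other cells, T and NK cell (adjusted p = 0.817), dendritic cell (adjusted p = 0.289) and monocyte genes (adjusted p = 0.307) were not called. Adjusted over the list alone, 5 dendritic cell genes rose and 2 fell, 2 monocyte genes fell, and 0 T and NK cell genes passed. Without replicate 3, 4 dendritic cell genes were called higher and 3 lower, 2 monocyte genes higher and 2 lower, and 1 T and NK cell gene higher and 1 lower. The 5 measured fibroblast, endothelial and epithelial markers were called higher with an adjusted p of 0.0424, with 0 single calls, also when adjusted over the list alone, 2 at an unadjusted p under 0.05 and 1 called higher without replicate 3, and had an adjusted p of 0.450 with an estimated correlation. Lists of B and plasma cells, neutrophils, granulocytes of other kinds and platelets had 3, 3, 1 and 2 measured genes and were not tested. In 7 lists, of which camera called 0, the median, the mean and the direction of the test differed in sign.

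**Figure D2:**
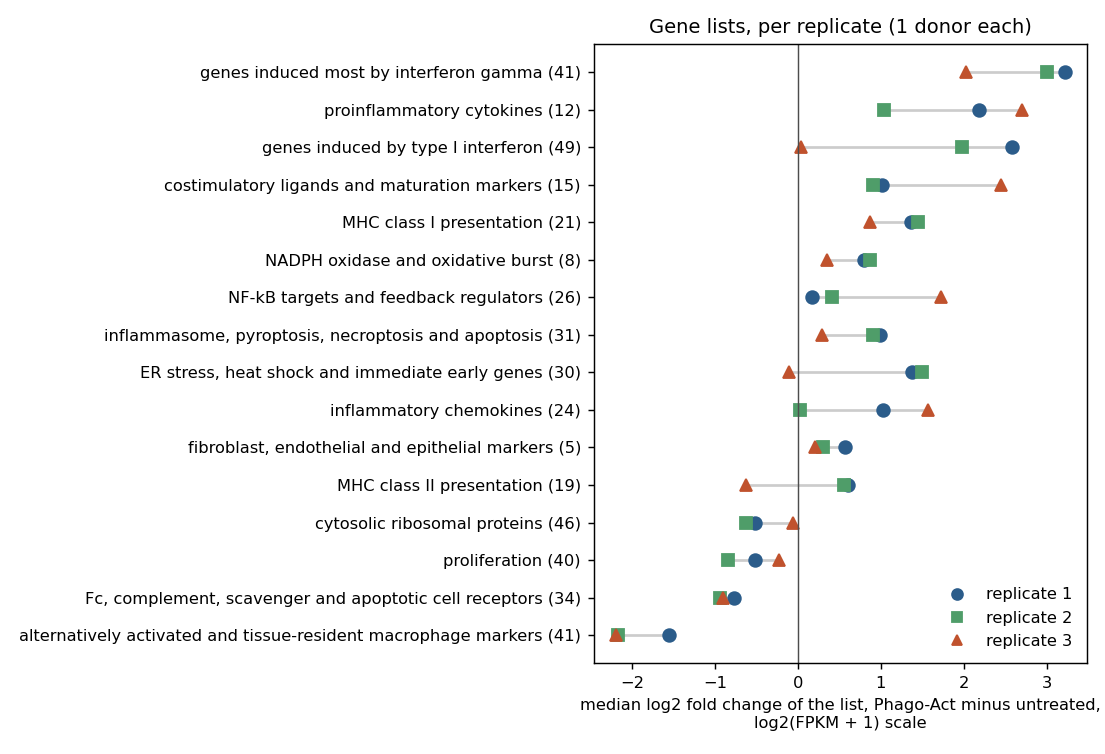
Median log2 fold change of each gene list (Phago-Act minus untreated, log2(FPKM + 1) scale) on the horizontal axis for the 15 lists that camera called with its preset correlation and for MHC class II presentation, with the number of measured genes in parentheses; each symbol is the median in 1 replicate, a pair of libraries of 1 donor. Symbols of replicate 3 lie apart for genes induced by type I interferon (0.04, against 2.58 and 1.98) and for MHC class II presentation (-0.62, against 0.61 and 0.55).

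The replicates differed in how far their responses resembled each other. In a principal component analysis of the 10697 genes, component 1 (46.4% of the variance) separated Phago-Act libraries, at 27.0 to 38.1, from untreated ones, at -38.2 to -28.6. Component 2 (28.4%) set the Phago-Act library of replicate 3, at -51.6, apart from those of replicates 1 and 2, at 24.4 and 27.2. Across genes, which are not independent replicates, the log2 fold changes of replicates 1 and 2 had a Pearson correlation of 0.840 (Spearman 0.779). Those of replicate 3 had a correlation of 0.290 with replicate 1 (Spearman 0.174) and of 0.339 with replicate 2 (Spearman 0.198). Between replicates 1 and 2, 7 genes changed at least 2-fold in opposite directions, against 114 between replicates 1 and 3 and 112 between replicates 2 and 3. At least 2-fold changes in the same direction in all 3 replicates were found for 144 genes that were higher and 163 that were lower.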

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

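The scalings, the filter at 5 FPKM, the fit without the trend and the fits that leave out libraries of replicate 3 without the donor block were chosen after seeing the data. All 39 called genes among those named kept their direction under every alternative run. This was largely fixed in advance. All 113 called genes had the same sign in all 3 replicates, so leaving out a whole replicate or changing the pseudocount could not reverse one. Counts of higher and lower genes stayed within 1.5 times of 65 and 48 with the 3 scalings, a pseudocount of 0.1, the filter at 5 FPKM and no trend. The fit with no replicate block called 180 higher and 176 lower (143 and 139 at least 2-fold). With no filter on low values 0 and 0 were called (0 and 0 at least 2-fold; 2713 at an unadjusted p under 0.05, lowest adjusted p = 0.0686, 16374 genes tested), and with adjusted p under 0.01 also 0 and 0. Leaving out 1 replicate gave 0 to 1367 higher and 0 to 1459 lower (0 to 565 and 0 to 440 at least 2-fold): limma called 0 without replicate 1 or 2 (1076 and 892 at an unadjusted p under 0.05) and the highest counts without replicate 3, where 65 and 48 of the 113 calls remained. These fits have 1 residual degree of freedom. With no replicate block and the Phago-Act library of replicate 3 left out, 545 were higher and 456 lower (323 and 265 at least 2-fold), and with both its libraries left out 724 and 525 (473 and 313). SIRPA stayed between 0.38 and 0.63 in log2 fold change and did not pass under any alternative (adjusted p = 0.0598 to 0.711). Camera called 11 lists higher and 4 lower; with an estimated correlation and with fry's directional test it was 0 higher and 0 lower each (lowest adjusted p 0.45 and 0.0813), while fry's test for change in either direction called 23 lists. Of the 15 called lists, 11 kept their call in every other fit with the preset correlation; proliferation genes, chemokines, NF-κB targets and the 5 fibroblast, endothelial and epithelial markers lost it in 1, 2, 2 and 4 fits. ISG20 and CLEC4E did not pass with a pseudocount of 0.1 (adjusted p = 0.078 and 0.076), nor ARG2, FABP4 and MS4A4A with median-of-ratios scaling (0.0525, 0.0525 and 0.0516). With the preset correlation and without replicate 3, camera also called cholesterol synthesis and matrix genes lower (adjusted p = 0.0311 and 0.0221) and pattern recognition genes higher (0.00866), without replicate 2 cholesterol synthesis and dendritic cell genes higher (0.0164 and 0.0244), and without replicate 1 monocyte genes lower (0.00641), so the direction of cholesterol synthesis genes depended on the replicate left out. The fit without the block changed no call of a named gene or list other than those given beside them. The cause of these differences was not tested. The planned fits that need counts (count models with their normalizations, limma-voom and filters on counts) were not run, because the values are FPKM. Without absolute depths, no limit of detection can be given for weakly expressed genes.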

Other observations

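Of the tests in this part, the splits of the libraries were planned; the tests on replicate 3, on SIRPA and on interferon-alpha genes, and the genes named here, were chosen after the result was seen.

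Some genes changed in opposite directions in replicate 3 and in replicates 1 and 2. Among genes that changed at least 2-fold in each replicate, 45 rose in replicates 1 and 2 and fell in replicate 3, and 27 did the reverse. FOS, an immediate early gene, went from 23.7 to 330 and from 35.8 to 421 FPKM in replicates 1 and 2, and from 132 to 1.06 FPKM in replicate 3. EGR1 (9 to 337, 21.2 to 458 and 92.3 to 1.23 FPKM) and NR4A1 (0.720 to 48.4, 3.33 to 32.7 and 31.3 to 0.60 FPKM) followed the same course, as did HLA-DMB, a chaperone of class II peptide loading (159.5 to 672, 153 to 472 and 216 to 76.6 FPKM). In the other direction, PTX3, an acute-phase pattern recognition protein, went from 22.4 to 0.50, from 29.1 to 0.210 and from 2.83 to 115 FPKM, and LPL, lipoprotein lipase, from 61.6 to 13.9, 99.2 to 9.60 and 94.7 to 515 FPKM. HSPA5, the gene of an ER stress chaperone, also took this course (253 to 118, 219 to 51.0 and 192 to 439 FPKM), opposite to FOS and EGR1. Not all early response genes followed FOS: ATF3 was higher with Phago-Act in all 3 replicates (65.7 to 154, 73.05 to 228 and 128 to 238 FPKM). IL12B, CCR7, LAMP3 and S100A8 also moved the same way in each replicate but reached different levels. For IL12B the value of replicate 1 was so low that its direction there carries little weight. With Phago-Act, IL12B, a subunit of interleukin-12, was listed at 0.0900, 1.35 and 179.5 FPKM, CCR7, a lymph node homing receptor, at 4.94, 53.3 and 222 FPKM and LAMP3, a dendritic cell maturation marker, at 5.90, 43.4 and 216 FPKM in replicates 1, 2 and 3. S100A8, a calcium-binding protein of monocytes, was at 28.99, 38.9 and 0.810 FPKM.

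Over whole lists, the median log2 fold change of replicate 3 minus the mean of replicates 1 and 2 was above all 10000 random lists of the same size matched on expression for 7 of the 32 lists. These were costimulatory and maturation genes (1.63), proinflammatory cytokines (1.42), NF-κB targets (1.22), dendritic cell markers (1.17), cholesterol synthesis (0.885), inflammatory chemokines (0.682) and proliferation (0.466). It was below all random lists for 4, which were genes induced by type I interferon (-2.35), ER stress and immediate early genes (-1.42), MHC class II presentation (-1.15) and genes induced by interferon gamma (-0.903). At most 0.03% of the random lists were lower than NADPH oxidase genes (-1.44), monocyte markers (-1.16), pattern recognition genes (-0.690) and genes of cell death (-0.626), and at most 0.03% were higher than matrix genes (0.666) and genes of lipid handling (0.564). Genes of a list can move together (estimated correlation 0.964 for type I interferon genes and 0.638 for MHC class II presentation), while randomly drawn genes need not. Medians of random lists can therefore spread too little, so lying outside them is no measure of significance. The values describe these libraries and are not a test across donors.

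With 3 libraries per group, the 10 splits of the 6 libraries are too few for a share under 0.05. Without the donor term, 1 of the 10 splits, the real one, called as many as 356 genes, and the highest other called 1. With the donor term, 1 of the 4 swaps of libraries within donors, the real one, gave 113 genes and the highest other 0.

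Why the Phago-Act library of replicate 3 lay apart was examined with 3 technical explanations. Lower sequencing depth would confine the distance to weak genes; among 1392 genes at 50 FPKM or more, the SD of its difference from the other Phago-Act libraries was 1.74 times that between those (95% bootstrap interval 1.47 to 2.08), which argues against it. Transcript length and GC content accounted for a share of 0.0146 of the variance over the genes that differed at least 2-fold (0.00648 to 0.0329), of which 98.6% had both values. The summed FPKM of T cell genes was 6.70 there, between 68.6 in replicate 1 and 1.45 in replicate 2 (log2 ratio -2.39 to their mean, but 2.21 to replicate 2 alone), and since the library with the highest sum lay beside that of replicate 2 on component 2 (24.4 and 27.2), T cells do not order these libraries as the distance does. A difference in the response between donors, in culture or in the treatment of that sample may remain, and 1 pair per donor cannot separate these.

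SIRPA was higher in each library labelled SIRPα low. A rise of the sum of SIRPB1, SIRPB2 and SIRPG at least as large as that of SIRPA was looked for as a sign of shared reads. The highest ratio of the changes was 0.432, and in replicate 3 the paralogs fell by 28.0 FPKM while SIRPA rose by 125 FPKM. This does not exclude shared reads, because paralog reads assigned to SIRPA would be missing from the paralogs, and how such reads were assigned is not given. The scaling of the FPKM does not account for the rise of SIRPA, with a lowest log2 fold change of 0.54 over the 3 other scalings against an SE of 0.18. As SIRPA did not pass the test (adjusted p = 0.204), the rise may be chance, and whether the label refers to SIRPα protein is open: protein was not analysed here.

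Genes induced by type I interferon had a smaller fold change in replicate 3. Over the 49 genes, its untreated library lay a median of 2.03 log2 units above the other untreated libraries, and its Phago-Act library a median of -0.20 from the other Phago-Act libraries. A smaller fold change must come from a higher untreated level, a lower treated level or both, so the values split the pattern into its parts and test no cause of it. The genes move together (estimated correlation 0.964, which leaves the weight of 1.04 independent genes), so the spread over genes sets no limits for 1 library. Why the levels differed was not tested.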
